A study of Panthera tigris amoyensis with 8 samples.

How the data were processed

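Whole blood RNA of South China tiger cubs was profiled on 8 arrays, 4 per feeding group. Per the labels' protocols, RNA was purified with a blood kit that lyses red and white cells separately, globin transcripts were depleted, and cRNA was labelled with the dye Cy3 from 0.5 ug of RNA. Depletion of globin transcripts limits what erythroid markers show. Per the submitters' processing notes, the images were read with Agilent Feature Extraction 9.1. Background correction, normalization and probe filters are not given in the sources used here.

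The deposited values are log2 levels. This unit was inferred from the values, which run from 0.577 to 18.9. All 8 columns hold the same set of sorted values, so the authors' deposited log2 values are quantile normalized, and array-wide differences in brightness are no longer visible in them. Of 22842 rows, 56 control probes were left out and 22786 target probes kept. Probe identifiers carry RefSeq accessions. Names came from an NCBI gene table for the assembly P.tigris_Pti1_mat1.1, matched without versions: 9256 probes matched a gene and 13530 did not, and 2030 of those matched carry only a locus name. Gene lengths are the genomic spans in the same table. No probe positions were used, since the array's build is not given in the sources used here. For genes with several probes (716), the probe with the highest mean over all 8 arrays was used, which left 8358 genes. Of 76 named genes, 9 have more than 1 probe, and 0 of these have another probe past the threshold in the opposite direction. Slide and scan batches are not given in the sources used here and were not tested.

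Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), artificial feeding minus natural breastfeeding, without covariates, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 32 gene lists, with 922 entries, were written before the data were examined, as were the groups, the tests and the naming rule. On the array 384 entries were measured. The 28 lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01, with an estimated correlation and fry beside it; none of the 7 lists past the threshold passed with an estimated correlation. The named genes are the 12 largest rises and 12 largest falls with an adjusted p under 0.05, no overlap between groups, a brighter group above the median of all probes and a gene symbol. For each list, up to 4 members past the threshold with the largest change were added, or, where none passed, up to 2 with the highest level; 1 gene that met this rule is not reported here. A probe counted as above background on an array when it exceeded the highest of 15 negative or dark control probes there, a limit between 2.63 and 3.48. For a group below background on all arrays a bound was computed from the higher of that limit and the measured level.

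On simulated data with the means and group SDs of the 8358 genes and 200 changed genes, limma recovered 61.2% of changes of 0.5 on the log2 scale, 94% of changes of 1 and 98.5% of changes of 2, with 18 unchanged genes called. A simulated shift of -0.5 in the T cell list was called. Genes were drawn independently of each other in these simulations. The list check therefore does not cover correlated members, and the measured T cell list had an estimated correlation of 0.338. Alternatives covered scaling, filters on dim probes, a floor at the 25th percentile, the variance model, array weights, the replicate number as a block, the mean of all probes of a gene, treat against a 1.5-fold change, other set tests and each array left out. The averaged nursed sample and a weight per group were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.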

Results

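Messenger RNA in the whole blood of South China tiger cubs was measured on one-colour Agilent oligonucleotide arrays. The study compared natural breastfeeding, in which the cub stayed with the tigress, with artificial feeding, in which cubs were taken away after birth and given colostrum for 48 hours and then a milk replacer. There were 4 arrays per group. By the labels, the 4 nursed arrays all hold blood of 1 cub. The labels give 2 accounts of the artificially fed arrays: the treatment protocol describes the mixed blood of 3 cubs divided into 4 portions, and the series design describes 4 cubs. Age is 4 months in the sample characteristics and 3 months in the protocol. The p-values below therefore compare the artificially fed arrays with portions of 1 nursed cub's blood and do not compare feeding regimes across animals. The number of arrays limits the precision. All values are log2 levels as deposited, and all changes are artificial feeding minus natural breastfeeding.

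Of 8358 genes tested, 442 passed an adjusted p of 0.05 in limma, 243 higher and 199 lower after artificial feeding, and 94 of them differed at least 2-fold (38 higher, 56 lower). At an unadjusted p under 0.05 there were 1740. Of 22786 probes, 1002 passed (509 higher, 493 lower). The groups did not overlap for 15.2% of genes, where chance gives 2.86% if all 8 arrays are independent. The 4 nursed arrays hold blood of 1 cub, so that reference does not apply here. GPA33, a cell surface antigen best known from intestinal epithelium, rose most among the genes with a symbol that met the naming rule, by 3.05 on the log2 scale (SE 0.254, adjusted p = 0.0014); its level was 3.05 ± 0.382 on nursed and 6.1 ± 0.383 on artificially fed arrays (SD, n = 4 each), and only 2 nursed arrays lay above background. ROPN1L, a ropporin-like protein of cilia and sperm tails, rose by 2.7 (SE 0.198, adjusted p = 0.000734). IL5RA, the interleukin 5 receptor subunit of eosinophils and basophils, rose by 1.63 (SE 0.12, adjusted p = 0.000734), with a further probe of the gene at 1.89. HNMT, which inactivates histamine, rose by 1.43, ERICH4 by 1.39, YPEL4 by 1.15, the decoy interleukin 1 receptor IL1R2 by 1.16, with a further probe at 0.58, and the neutrophil collagenase MMP8 by 1.12. YPEL4 passed in 1 of the 8 fits that leave out 1 array each (adjusted p up to 0.103), and the others named here passed in all 8.

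Complement subunits were among the genes that fell. C1QB fell by 2.12 (SE 0.376, adjusted p = 0.0227), C1QC fell by 1.94 with 3 of 4 artificially fed arrays above background, and C1QA fell by 1.57 (SE 0.343, adjusted p = 0.0447). C1QB did not pass without any 1 nursed array or without artificial feeding replicate 2, and C1QA passed only without artificial feeding replicate 1 when single arrays were left out (adjusted p up to 0.0673 and 0.111). CAV2, a caveolin, fell by 1.78 (adjusted p = 0.00501). TNFSF10, the death ligand TRAIL, fell by 1.61, SLAMF8 fell by 1.58, the nuclease gene DNASE1L3 fell by 1.56 and CD274, which encodes the checkpoint ligand PD-L1, fell by 1.54. TRANK1 fell by 1.46 and VWA5A fell by 1.42. TNFSF10 passed in 6 of the 8 fits that leave out 1 array each (adjusted p up to 0.0537). The naming rule required that each of these 10 genes be lower on all 4 artificially fed arrays than on any nursed array. When the 4 nursed arrays were averaged to 1 sample, a setting chosen after the data were seen, 4 genes passed in limma, with 649 at an unadjusted p under 0.05; the lone nursed sample is assumed to vary like the other group. Of these, PAK5 and the unnamed locus LOC107178969 are among the 442, while LOC102956321 and LOC102964157 did not pass with 4 nursed arrays (adjusted p = 0.58 and 0.101). All 4 were lower and are named here after their values were seen.

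**Figure D1:**
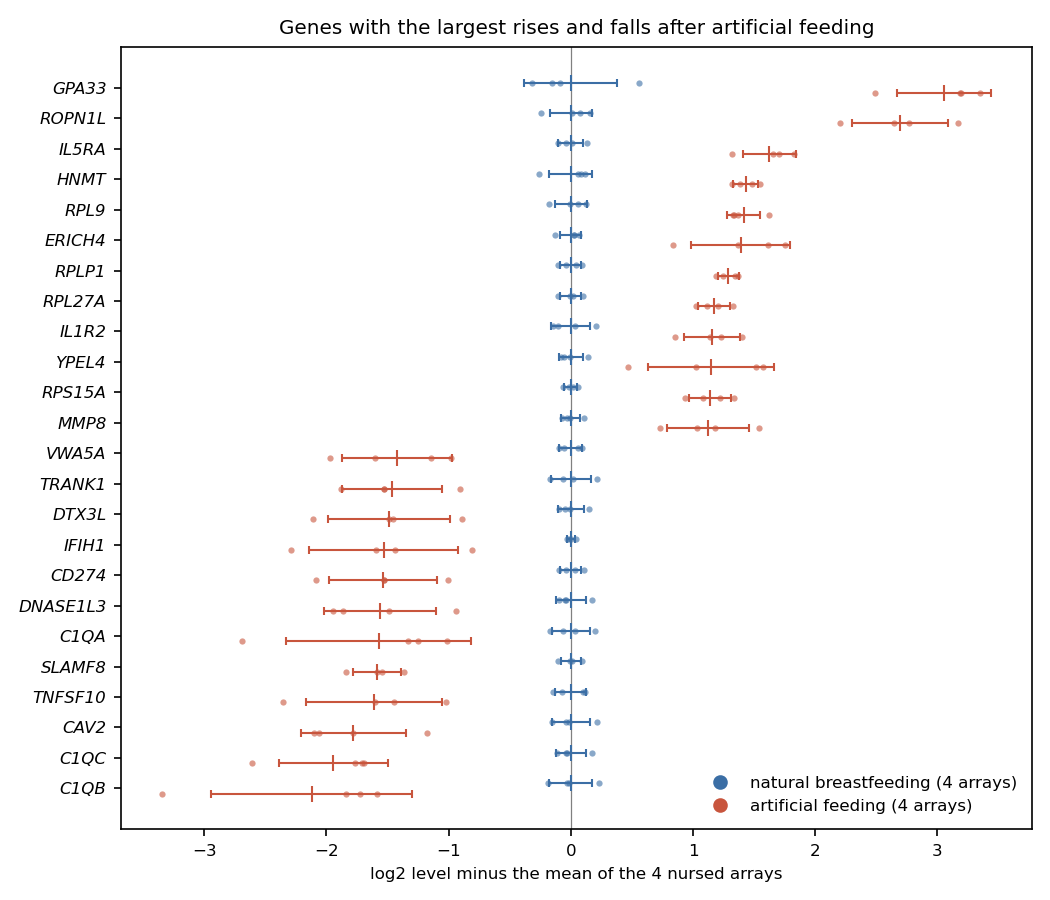
Log2 level on each array minus the mean of the 4 nursed arrays (horizontal axis) for the 12 largest rises and 12 largest falls that met the naming rule; points are arrays, vertical ticks are group means and bars are SDs over 4 arrays. For GPA33 the groups differ by 3.05, and for C1QB the artificially fed mean fell by 2.12, with 1 array well below the other 3.

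Genes of the type I interferon response, which cells use against viruses, were lower after artificial feeding. Of 18 measured list members, 17 had a lower mean, 5 passed the threshold over all genes, all lower, and 17 were lower when adjusted over the list alone. IFIH1, a sensor of double-stranded RNA, fell by 1.53 (SE 0.271, adjusted p = 0.0227), DTX3L fell by 1.49 (adjusted p = 0.0139), ZBP1 fell by 1.33 (adjusted p = 0.0456) and SAMD9L fell by 1.12 (adjusted p = 0.0323). With 1 array left out, IFIH1 passed in 3 of 8 fits and ZBP1 and SAMD9L in 2 each (adjusted p up to 0.0688, 0.117 and 0.0931). The list median was -1.48 (camera adjusted p = 2.89e-09). The list did not pass with an estimated correlation (adjusted p = 0.499 with an estimated correlation), and fry gave an adjusted p of 0.064. The artificially fed arrays differed from each other. The list median relative to the nursed mean was -2.58 on replicate 1, -1.3 on replicate 2, -0.7 on replicate 3 and -1.41 on replicate 4. RSAD2, named after its values were seen, had log2 levels of 0.62, 8.12, 8.69 and 7.32 on artificially fed replicates 1 to 4 and 10.38 to 10.79 on the nursed arrays, and did not pass (adjusted p = 0.181). Without artificial feeding replicate 1, 14 of the 18 genes passed and the list median was -1.16. Without nursed replicate 1 or artificial feeding replicate 2, 2 genes passed, without nursed replicate 2, 3 or 4, 1 passed, and without artificial feeding replicate 4, 3 passed.

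**Figure D2:**
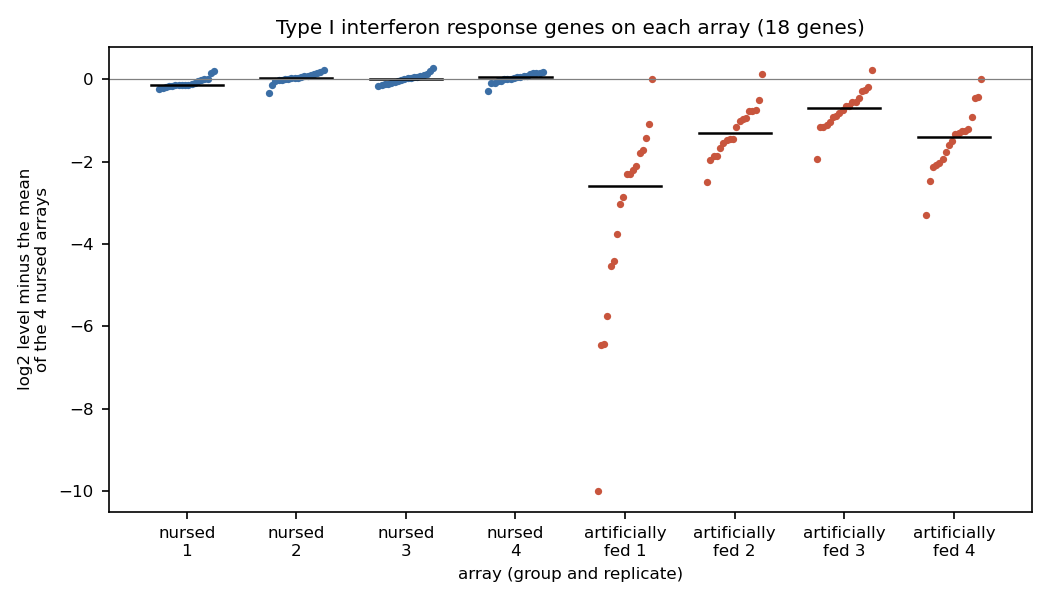
Log2 level minus the mean of the 4 nursed arrays (vertical axis) for the 18 type I interferon response genes on each of the 8 arrays; points are genes and black lines are medians. The median is -2.58 on artificially fed replicate 1 and -0.7 on artificially fed replicate 3.

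Antigen processing for MHC class I moved the same way. All 8 measured members had a lower mean, 3 passed, and 7 were lower when adjusted over the list alone (list median -0.43, camera adjusted p = 9.45e-06; adjusted p = 0.499 with an estimated correlation). TAP1, the peptide transporter subunit, fell by 0.92 (SE 0.143, adjusted p = 0.0146), and the proteasome activator subunits PSME1 and PSME2 each fell by 0.43; with 1 array left out they passed in 6, 2 and 2 of 8 fits (adjusted p up to 0.0519, 0.0938 and 0.0998). No more than 1 MHC class I gene passed without any 1 nursed array or without artificial feeding replicate 2 or 4. In the complement list, 3 of 14 members passed, which were the C1q genes above, and 3 were lower when adjusted over the list alone (median -0.17, camera adjusted p = 0.0154; adjusted p = 0.499 with an estimated correlation). A single member passed without any 1 nursed array or without artificial feeding replicate 2. The complement list was not past the threshold when only the brighter 50% of probes were kept (adjusted p = 0.14). All 10 heat shock and protein folding genes had a lower mean, but 1 passed and 2 were lower when adjusted over the list alone (median -0.26, camera adjusted p = 0.00146; adjusted p = 0.499 with an estimated correlation). That gene, the endoplasmic reticulum chaperone HSP90B1, fell by 0.64 (adjusted p = 0.00923). In MHC class II, 4 genes were measured, too few for the list test, and CD74, the invariant chain, fell by 1.05 (SE 0.136, adjusted p = 0.00828).

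Of 46 cytosolic ribosomal protein genes measured, 10 rose and 0 fell, 17 were higher when adjusted over the list alone, 33 had a higher mean and 13 a lower mean (median 0.2, camera adjusted p = 1.16e-06; adjusted p = 0.499 with an estimated correlation). RPL9 rose by 1.41 (SE 0.0914), RPLP1 by 1.29 (SE 0.0733), RPL27A by 1.17 (SE 0.0805) and RPS15A by 1.14 (SE 0.0849). Mitochondrial oxidative phosphorylation genes did not pass as a list (median 0.1, camera adjusted p = 0.072), with 4 of 23 higher. These were NDUFA4, NDUFA2, NDUFB5 and NDUFA6, which rose by 0.44, 0.42, 0.39 and 0.34. They passed in 2, 8, 7 and 6 of the 8 fits that leave out 1 array each (adjusted p up to 0.0903 for NDUFA4). In that list 2 members passed without natural breastfeeding replicate 2 and 1 without natural breastfeeding replicate 4, and the list passed without artificial feeding replicate 4 (median 0.09, adjusted p = 0.0443) and with the nursed arrays averaged (adjusted p = 0.0304).

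Among blood cell type markers, the B cell list was lower, with 3 of 11 members past the threshold (median -0.31, camera adjusted p = 0.00191; adjusted p = 0.499 with an estimated correlation); adjusted over the list alone, 5 were lower and 1 was higher. No member passed without any 1 nursed array or without artificial feeding replicate 2 or 3, 1 passed without artificial feeding replicate 4 and 5 without artificial feeding replicate 1. BLNK fell by 0.44, TNFRSF13B fell by 0.4 and MS4A1, which encodes CD20, fell by 0.31, with adjusted p up to 0.0762, 0.0871 and 0.13 when 1 array was left out. In the T cell list 2 of 14 passed and 3 were lower when adjusted over the list alone (median -0.16, camera adjusted p = 0.041; adjusted p = 0.564 with an estimated correlation). CD3E, a chain of the T cell receptor complex, fell by 0.83 (SE 0.122, adjusted p = 0.0124) and the transcription factor LEF1 fell by 0.59, with a dimmer probe of the gene at -0.2 (adjusted p = 0.423 over probes). LEF1 passed in 4 of the 8 fits that leave out 1 array each (adjusted p up to 0.0686). The T cell list was not past the threshold without natural breastfeeding replicate 1 (adjusted p = 0.0784), without artificial feeding replicate 3 (adjusted p = 0.109) or without artificial feeding replicate 4 (median 0.02, adjusted p = 0.374). Nor was it with the brighter 50% of probes (adjusted p = 0.106), with array weights (adjusted p = 0.0611) or in fry (adjusted p = 0.257). A single T cell gene passed without natural breastfeeding replicate 1, 3 or 4 or without artificial feeding replicate 3. Neutrophil markers moved in both directions: MMP8 and S100A8, a calgranulin, rose, the latter by 0.91, while the interleukin 8 receptor CXCR1 fell by 0.96 (list adjusted p = 0.597). Among monocyte markers, CD14 rose by 0.83 and CX3CR1 by 0.53, and TLR4 fell by 0.44 (list adjusted p = 0.698). With 1 array left out, CX3CR1 and TLR4 passed in 2 of 8 fits each (adjusted p up to 0.0856 and 0.118), and CD14 alone passed without any 1 nursed array or without artificial feeding replicate 2. In the dendritic cell list TCF4 fell by 0.56 (list adjusted p = 0.611) and passed in 4 of 8 such fits (adjusted p up to 0.0688).

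No member passed in limma among plasma cell, NK and cytotoxic cell, platelet and megakaryocyte or erythroid markers. Their list medians were -0.02, 0.05, -0.37 and 0.04. The platelet median relative to the nursed mean was -1.08, -1.07, 0.07 and 0.44 on artificially fed replicates 1 to 4; the list median was -0.67 without replicate 4, where the list passed (adjusted p = 0.0255), and -0.13 without replicate 1. The NK median was -0.15 without artificial feeding replicate 1. With single arrays left out, 1 NK and 1 platelet member passed without artificial feeding replicate 4 and 2 erythroid members without artificial feeding replicate 1. The changes were -0.15 for TNFRSF17, -0.06 for JCHAIN, -0.44 for GZMH, -0.52 for GZMK, -0.37 for VWF, -0.74 for ITGA2B and 0.06 for EPB41. Of 4 eosinophil and basophil markers, IL5RA alone passed. Among 12 markers of skin, muscle, liver and gut, which blood should lack, VIL1, the villin gene, rose by 0.96 (SE 0.101, adjusted p = 0.00458). None of the 10 sex-linked genes was measured.

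**Figure D3:**
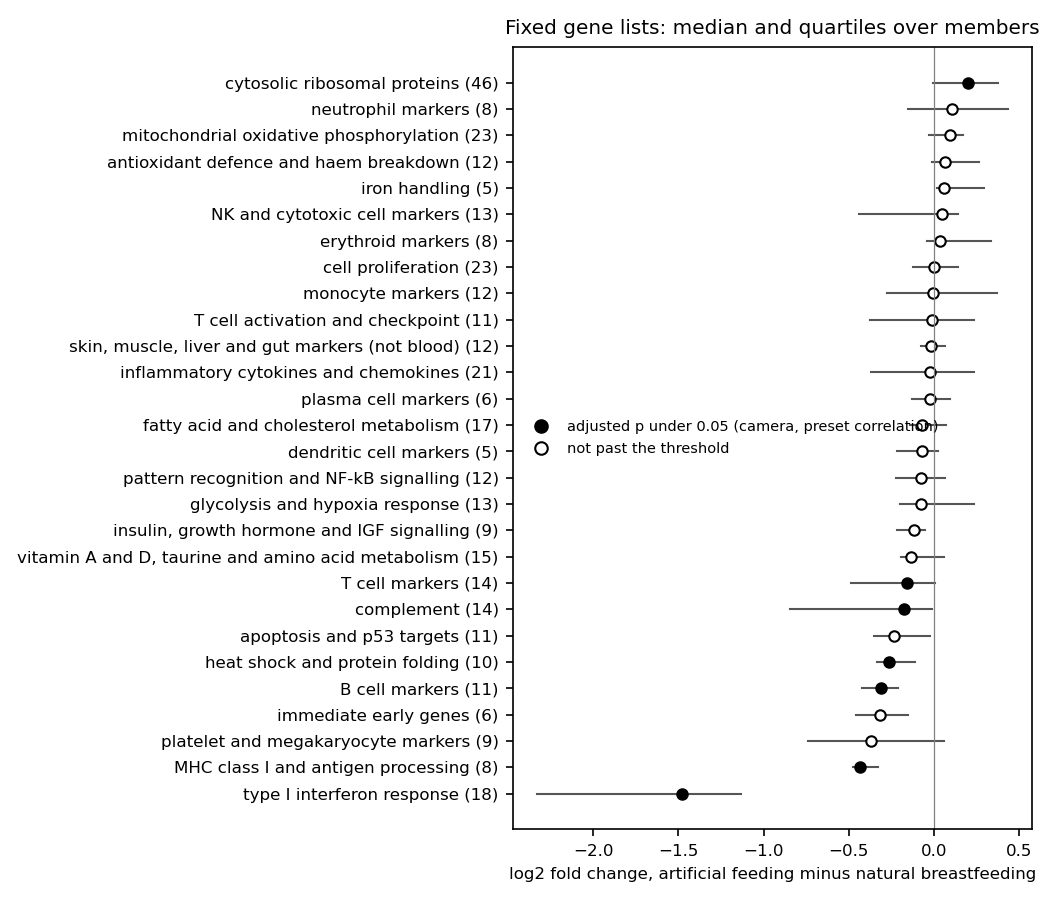
Median log2 fold change over members (points) with lower and upper quartiles (lines) for the 28 gene lists tested, numbers of measured genes in parentheses; filled points mark a camera adjusted p under 0.05. The interferon list lies lowest at -1.48 and the ribosomal protein list highest at 0.2.

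The remaining lists did not pass camera with all 8 arrays. Of 21 inflammatory cytokine and chemokine genes, IL1R2 rose, and IL1A, OSM and PTGS2 were lower; IL1A fell by 0.78 (adjusted p = 0.00719) and PTGS2, a prostaglandin synthase, fell by 0.72. OSM lay above background on 1 nursed array only and has no fold. In the pattern recognition list TLR7, a receptor for single-stranded RNA, fell by 0.58, and in the T cell activation list IL2RG fell by 0.55. Among immediate early genes FOS rose by 0.48 and EGR2 fell by 0.8, and that list passed without artificial feeding replicate 4 (adjusted p = 0.0255) and with the nursed arrays averaged (adjusted p = 0.0276). In the apoptosis list BCL2L11, which encodes the pro-apoptotic BIM, fell by 1.14, MCL1 fell by 0.32 and BCL2A1 rose by 0.32 (list camera adjusted p = 0.103, fry adjusted p = 0.00171; adjusted p = 0.499 with an estimated correlation). No apoptosis member passed without nursed replicate 2, 3 or 4, and 1 passed without nursed replicate 1 or artificial feeding replicate 2 or 3. CHAC1, which degrades glutathione, fell by 1.23 and ARG2, a mitochondrial arginase, rose by 0.3 in the list of vitamin, taurine and amino acid metabolism. FADS1, a fatty acid desaturase, rose by 0.42 and the metal transporter SLC11A1 rose by 0.44. Of 4 measured glucocorticoid-induced genes, too few for the list test, the kinase gene SGK1 fell by 0.38 and IL1R2 rose by 1.16. IGFBP4, the gene past the threshold in the insulin and growth hormone list, lay below background on all 8 arrays (list camera adjusted p = 0.164, fry adjusted p = 0.0207; adjusted p = 0.499 with an estimated correlation). With 1 array left out, IL1A and CHAC1 passed in all 8 fits and EGR2 in 7. SLC11A1 passed in 5, FOS, IL2RG and MCL1 in 4, OSM and BCL2A1 in 3, BCL2L11, SGK1 and ARG2 in 2, and PTGS2, TLR7, FADS1 and IGFBP4 in 1, with adjusted p up to 0.132. No member passed in limma in the glycolysis, proliferation or antioxidant lists, whose medians were -0.08, -0.00049 and 0.06; the antioxidant list passed without artificial feeding replicate 1 (median 0.2, adjusted p = 0.0159, 2 members past the threshold), as did 1 glycolysis member, and 1 proliferation member passed without artificial feeding replicate 2. The changes there were -0.42 for ALDOA, -0.2 for HK1, -0.14 for PCNA, -0.07 for PRDX5 and 0.57 for PRDX2.

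Some probes matched no gene symbol. The probe XM_007080463.2_564_10 was below background on the nursed arrays and at least 20.2-fold higher after artificial feeding (adjusted p = 0.000124), and XM_007091007.2_2208_5 was at least 13.7-fold lower, being below background on the artificially fed arrays (adjusted p = 0.00211). The locus LOC107178969 was at least 18.2-fold lower (adjusted p = 2.01e-06 over probes).

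The artificially fed arrays spread more than the nursed arrays. Over 11363 probes above the median level, the median SD was 0.171 against 0.12, and 86 probes had an SD over 1 against 0. Correlations between arrays across probes, which are not independent replicates, were 0.9925 to 0.9935 within the nursed group, 0.9842 to 0.9923 within the artificially fed group and 0.985 to 0.9897 between groups. The counts depended on single arrays: 164 genes passed without natural breastfeeding replicate 2 and 513 without artificial feeding replicate 1. The number of lists past the threshold, 7, was matched or exceeded in 6 of the 35 ways of splitting the 8 arrays into 4 and 4, the real one included.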

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

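The tests that weigh explanations for the spread among artificially fed arrays and for the interferon genes were chosen after those results had been seen; the list tests, the fits without single arrays, the tests of the ribosomal list and those of other splits were chosen before. In each group of 4 arrays, a named gene is listed here when its highest or lowest array lay far from the other 3, measured as the gap over the whole range. Of 152 groups, 8 met this, where chance gives about 1 in 20, or 7.8. On artificially fed replicate 1, C1QB (0.859) and C1QC (0.92) lay low, at log2 levels of 3.38 and 2.59. RPL9 lay high on artificially fed replicate 2 (0.861), FOS lay low on replicate 3 (0.832) and SLC11A1 lay low on replicate 4 (0.846). Among nursed arrays, HNMT lay low on replicate 3 (0.836), CD3E lay high on replicate 3 (0.887) and PRDX5 lay high on replicate 1 (0.873).

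The artificially fed arrays differed among themselves: 86 bright probes had an SD over 1 against 0 among the nursed arrays, which argues against portions of a mixed pool that differ as little as the portions of the nursed cub's blood. For genes with several bright probes, faults of single spots are argued against by the median correlation of probe pairs over these arrays, 0.988 in 26 pairs. Array-wide labelling differences were tested by the ratio of the median spike-in SDs, artificially fed over nursed. It was 1.27, between the bounds of 1 and the 1.43 of bright probes, and leaves that account open for the general spread. A further test was added only once this had been read and covers the probes with an SD over 1. No spike-in probe exceeded an SD of 0.245 among the artificially fed arrays. Both tests use the quantile normalized values, in which array-wide brightness differences no longer show, so neither can decide that account. Spike-ins do not report on RNA quality before labelling, so a pool whose portions differed in RNA quality stays open and was not tested. At 6 bright probes 1 artificially fed array lay at least 16-fold from the other 3, which lay within 1 of each other on the log2 scale (9 probes without that limit), against 0 among nursed arrays either way; 1 of the 6, for IFIT2 (named after its values were seen), was low on replicate 1 along with other interferon genes, spot faults stay open for the 5 that have no gene name, and the series design's account of a different cub per array stays open.

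The interferon list was lower by camera with a preset correlation, with 5 of 18 genes past the threshold, but it did not pass in 2 other tests (adjusted p = 0.499 with an estimated correlation, fry adjusted p = 0.064). Replicate 1 alone does not account for the lower levels, since the list median without that array was -1.16. Of 9 cell type marker lists, that of platelets had the lowest median, -0.37. It lay above the upper quartile of the interferon genes at -1.13. For T and B cells, with most listed markers above background, this argues against a smaller share of that cell type as the sole account of the interferon fall. A smaller share as such stays open, since the B and T cell lists had medians of -0.31 and -0.16. Lists with dim members cannot decide this: in the dendritic list XCR1, CCR6 and CLEC9A had mean levels of 1.44, 2.31 and 2.76. Cell types without a list stay open, and no macrophage list was tested. The C1q genes, SLAMF8 and SIGLEC1, a macrophage lectin named after its values were seen, were also lower on all artificially fed arrays. Over these arrays SIGLEC1 followed the order of the interferon list medians, lowest on replicate 1 and highest on replicate 3. Its fall therefore does not separate fewer macrophages from lower interferon response genes. Platelet markers were at -1.08 and -1.07 on artificially fed replicates 1 and 2 (list median -0.67 without replicate 4, -0.13 without replicate 1), but at 0.07 and 0.44 on replicates 3 and 4, where the interferon genes were at -0.7 and -1.41. The feeding regime cannot be told apart from the individual cub, because the nursed group holds 1 cub; an infection or other state of that cub may be involved and was not tested.

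The ribosomal protein list was higher by camera with a preset correlation, with 10 of 46 genes past the threshold and 13 with a lower mean (adjusted p = 0.499 with an estimated correlation). Its mean change lay at percentile 100 of 10000 random lists matched on level and genomic gene length, although the list stayed brighter than its matches (median level 14.6 against 13.5), which argues against a trend with genomic gene length. Other genes as bright had a median change of -0.0518, which argues against a shift of all bright probes. RNA quality and the share of cell types were not tested for this list, and the feeding regime stays open.

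Other groupings of the arrays were examined over the 35 splits into 4 and 4. For probes, genes and genes at least 2-fold apart, 1 split, the real one, gave as many (1002, 442 and 94). The highest of the other splits gave 3, 2 and 1. The 4 nursed arrays are portions of 1 cub's blood and resemble each other whatever sets the groups apart. The splits therefore cannot decide whether these counts arose by chance, and a chance difference between cubs cannot be excluded. For the lists, 6 splits, the real one included, gave as many as 7 and the highest other gave 8. The real split does not stand out for that count. The interferon list passed in 24 of the 35 splits, and 5 splits, the real one included, gave a p as low as the real one. For the ribosomal, MHC class I and complement lists only the real split gave a p as low. Counting the real split, 2 splits did so for heat shock, 4 for B cells and 10 for T cells. These lists also passed the threshold in many of the 35 splits. The ribosomal list passed in 15, MHC class I in 10 and complement in 7, the real split included. Heat shock passed in 12, B cells in 10 and T cells in 11.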

How the results depend on the processing

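The settings that average the nursed arrays or weight the groups were chosen after the data were seen. The values arrive quantile normalized, so the scaling alternatives move almost nothing and test little. Of 1002 probes, 442 genes and 94 genes at least 2-fold apart, array weights gave 1680 probes and 746 genes; averaging the nursed arrays gave 39, 4 and 4, with fewer samples by construction, and 9 lists against 7, the further ones being oxidative phosphorylation (adjusted p = 0.0304) and immediate early genes (adjusted p = 0.0276); treat against a 1.5-fold change gave 16 genes. Of 7 lists, camera with an estimated correlation gave 0, and fry gave 4, of which 2 (MHC class I and ribosomal proteins) were among the 7. With single arrays left out, probes ranged from 296 to 1175, genes from 164 to 513, genes at least 2-fold apart from 55 to 140 and lists from 6 to 9; the lowest gene count came without natural breastfeeding replicate 2 and the highest without artificial feeding replicate 1, where 339 of the 442 genes stayed past the threshold with the same sign. The replicate block gave 84 probes, 141 genes and 49 genes at least 2-fold apart. Replicate numbers do not pair the arrays: deviations of same-numbered arrays correlated at 0.24, 0.047, 0.0085 and -0.05, and not every array correlated best with its own number.

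Of 63 named genes past the threshold, 0 changed sign under 20 settings. The groups of these genes do not overlap, so leaving out, averaging or weighting arrays could not turn a sign, and the 0 says little. Of the 63, 22 passed under every setting other than the averaged one. The T cell list was at an adjusted p of 0.052 with the replicate block, and its median turned to 0.024 without artificial feeding replicate 4. The other directions that turned belong to results not past the threshold. CCNB1 was 0.13 with array weights and ranged from -0.078 to 0.093 with single arrays left out. EPB41 was -0.075 with the mean of all probes and ranged from -0.046 to 0.192 with single arrays left out. The direction of the list test turned for fatty acid and cholesterol metabolism (median -0.0601 with the brighter 50% of probes, -0.0678 with fry) and for cell proliferation (0.0825 with array weights, -0.00049 with fry). It also turned in some of the fits that leave out an array, where medians ranged from -0.119 to -0.00078 for fatty acid and cholesterol metabolism, -0.0613 to 0.0307 for cell proliferation, -0.0997 to 0.0379 for plasma cells, -0.148 to 0.0621 for NK and cytotoxic cells, 0.00866 to 0.136 for erythroid markers, -0.271 to 0.0146 for dendritic cells, -0.16 to 0.123 for glycolysis and hypoxia, and -0.0192 to 0.0126 for skin, muscle, liver and gut markers. The cause was not tested. Dim probes limit the rest: between 34.7% and 41.4% of target probes lay below background on each array.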

Other observations

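Several genes outside the lists differed widely among the artificially fed arrays while the nursed arrays stayed close together; they are named after their values were seen, and no explanation is given for any of them. OPALIN, a myelin gene, had log2 levels of 9.61, 9.06, 4.61 and 10.18 on artificially fed replicates 1 to 4 and 4.24 to 4.68 on nursed arrays, and did not pass in limma (adjusted p = 0.094). MYLPF, a muscle myosin light chain, had levels of 4.32, 5.65, 7.57 and 8.63 against 5.7 to 6.06. MGST1, a microsomal glutathione transferase, had levels of 5.6, 7.65, 8.16 and 7.67 against 6.01 to 6.2, and a further probe of the gene gave 4.11, 6.68, 7.18 and 6.62. ADCK2 was at 11.01 on artificially fed replicate 3 and between 8.56 and 8.7 on the other 3. SIGLEC1, a macrophage lectin, had levels of 3.43, 6.19, 6.98 and 5.95 against 8.06 to 8.56, in the same order over the artificially fed arrays as the interferon list medians.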
